A study of Mus musculus with 8 samples.

How the data were processed

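Bone marrow-derived macrophages of 2 genotypes, wild type and Rbpj knockout in LysM-Cre expressing cells, were sampled at day 0 and after 2 days with TNF at 40 ng/ml, with 2 libraries in each of 4 groups. Per the labels' protocols, total RNA was purified on columns and poly-A RNA was made into libraries. Per the submitters' processing notes, fastp, HISAT2, HTSeq and edgeR were used with genome build mm10. Their versions, settings and gene annotation were not given in the sources used here. The deposited values are CPM, scaled by the reads counted in genes of each library, in 1 table of 24421 genes. Of the symbols in the table, 27 had been turned into dates, 4 of which share a symbol, and 23350 are symbols in GENCODE M21, from which the GRCm38 positions were taken. Mitochondrial genes were not analysed here.

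The CPM were whole multiples of the value of 1 read in every library (100% of values within 0.01 of a whole number), so reads were recovered and library sizes taken from them. Depth ranged from 9855859 to 35653203 reads, and from 14491 to 15773 genes had at least 1 read. The counts of the 2 libraries of each group differed by more than sampling noise, so none was counted as a repeat. Intervals for genes with few reads are 95% counting intervals of the ratio of 2 groups' summed reads, and cover counting error only.

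The groups, contrasts, filters, tests, gene lists and rule for named genes were fixed before the data were examined. The test was limma (lmFit and eBayes with trend, 2-sided) on log2(CPM + 0.5), over the 12194 genes with at least 1 CPM in at least 2 libraries (49.9% of the table), with group as the only term. All 8 libraries shared 1 estimate of the spread, with 4 residual degrees of freedom. Log2 differences are on the log2(CPM + 0.5) scale, which understates the change of low genes. A ± after a log2 value is the moderated standard error of the limma fit, with the block where the text says so. A ± after a CPM value is the SD of the 2 libraries. Benjamini-Hochberg adjustment ran over all genes of each of 5 contrasts, with a threshold of adjusted p = 0.05. The contrasts were TNF against day 0 in each genotype, knockout against wild type at each time, and the difference of the TNF responses. edgeR (quasi-likelihood) and DESeq2 were run on the recovered reads as alternatives. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

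The replicate numbers were treated as pairing the libraries, and this was decided before the calls of the fits were compared. The series design states 2 independent experiments and each group has 1 library of each number, but no label says outright that the number marks the experiment. The differences between replicates 2 and 1, across genes, correlated between every pair of groups (6 pairs, Pearson r 0.577 to 0.805, across genes, which are not independent replicates), and the second principal component separated the numbers. Values from the fit with the replicate number as a block, which leaves 3 residual degrees of freedom, therefore stand beside those without it where they change a call or a count.

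Named genes were Rbpj, up to 10 with the largest increase and 10 with the largest decrease among those past the threshold with a mean of at least 2 CPM and no overlap between the groups, up to 4 members of each list, and 14 genes fixed by name. Some of the genes so named are not reported here. Predicted and unnamed genes were skipped. The same rule was also applied to the fit with the block, a step added after the data were seen. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists with at least 4 genes kept, of 36 lists written. Lists of mitochondrial transcripts, T and NK cell markers and histone genes were not tested, with 0, 2 and 1 genes kept. Camera was repeated with a correlation estimated from the data, and members were also adjusted over the list alone. The estimate rests on the 4 residual degrees of freedom of the fit, or 3 with the block. With so few, the test has little power, and a call lost there does not show that a list was unchanged. Genes of near-identical copies, such as Lyz1 and Lyz2, are uncertain because the counting of shared reads was not stated.

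The fits were tested on simulated reads drawn from these libraries' means and sizes, for knockout against wild type after TNF over 11948 genes, with 50 genes changed at each fold. Without the block, limma recovered 0% of 2-fold, 4% of 4-fold, 50% of 8-fold and 76% of 16-fold changes, with 0 unchanged genes called. With the block it recovered 42% of 2-fold and 100% of 4-fold, 8-fold and 16-fold changes, with 6 unchanged genes called. For edgeR with the block it was 40% of 2-fold and 100% of the larger folds, with 5 unchanged genes called. The simulated reads carried the same replicate difference in every group and a common spread for all genes. The block assumes such a replicate difference, so its gain over the fit without it was built in. Replicate differences that vary between groups, and spreads that vary between genes, were not simulated. Alternatives were pseudocounts of 0.1 and 2, no filter, a filter at 5 CPM, median-ratio and quantile scaling, other limma settings, the 4 libraries of a contrast alone, and leaving out each library. Groups of 2 are too small for a test of single libraries standing apart or for other splits of the samples.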

Results

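Gene expression was measured by poly-A RNA sequencing in bone marrow-derived macrophages (BMMs), cells grown from mouse marrow precursors. The cells were wild type or lacked Rbpj in the myeloid lineage, through Cre expressed from the LysM (Lyz2) locus. RBP-J, the product of Rbpj, is the DNA-binding partner of the Notch receptors. Each genotype was sampled at day 0 and after 2 days with TNF at 40 ng/ml, and each of the 4 groups held 2 libraries. No group was kept for 2 days without TNF, so TNF and 2 days in culture cannot be told apart. Where the text names TNF as raising or lowering genes, time in culture is included. The libraries held 27437659 and 26956109 reads for wild type at day 0, 35653203 and 23581922 for wild type with TNF. They held 27982448 and 22510387 for the knockout at day 0, and 9855859 and 18962533 for the knockout with TNF. The comparisons asked what TNF changed in each genotype, what the loss of Rbpj changed at each time, and whether the TNF response differed with Rbpj loss. The first principal component held 44.9% of the variance and the second, which separated replicate 1 from replicate 2 in each group, held 32.9%. No label says that the 2 libraries of a group came from separate animals, so p-values measure the spread between these samples.

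The targeted gene had a lower level in each knockout library than in any wild-type library. Hes1, a transcriptional repressor and classical Notch target, had few reads in wild type and more in the knockout. Rbpj (ENSMUSG00000039191.12, GRCm38 chromosome 5, 53466152 to 53657362, protein coding) stood at 215 and 216 CPM in wild type at day 0 and 226 and 178 CPM with TNF. In the knockout it stood at 38.9 and 31.8 CPM at day 0 and 30.0 and 21.4 CPM with TNF. The log2 difference was -2.60 ± 0.27 at day 0 (limma adjusted p = 0.238, and 0.0264 with the replicate number as a block) and -2.96 ± 0.27 after TNF (adjusted p = 0.0735, and 0.00339 with the block). The blocked call after TNF was lost without wild-type TNF replicate 2 (adjusted p = 0.0828). At day 0 it was lost when 1 of 6 libraries was left out, wild-type day 0 replicate 1 or 2 (adjusted p = 0.142 and 0.314), wild-type TNF replicate 1 or 2 (0.0981 and 0.111) or knockout day 0 replicate 1 or 2 (0.105 and 0.729). Hes1 (ENSMUSG00000022528.8, chromosome 16, 30064384 to 30067796) had 5 reads over both wild-type day 0 libraries and 418 over both knockout libraries, a ratio of 90.1 (95% counting interval 38.3 to 279). Its day 0 difference did not pass the adjusted threshold (limma adjusted p = 0.238, and 0.0835 with the block). TNF lowered Hes1 in the knockout from 8.17 ± 1.44 to 1.57 ± 0.359 CPM (mean ± SD, n = 2, limma adjusted p = 0.0341), a call lost when any 1 of the 8 libraries was left out (adjusted p 0.0504 to 0.217).

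**Figure D1:**
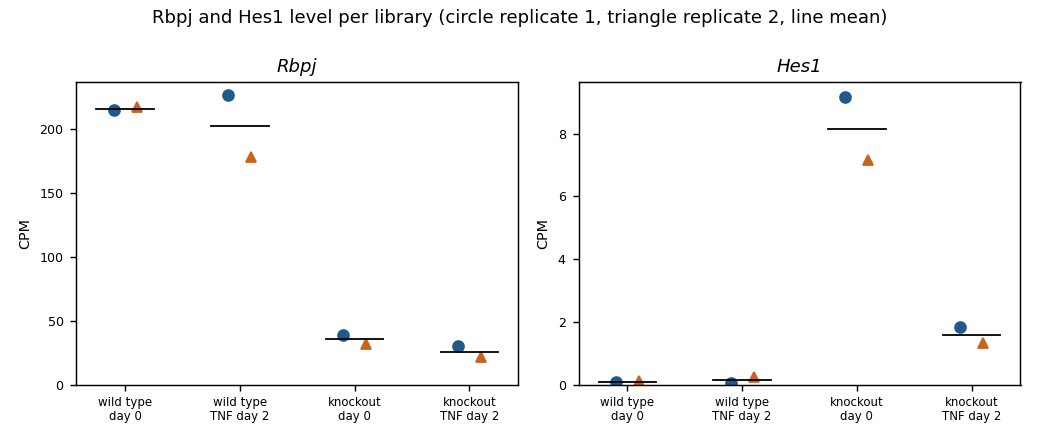
Rbpj (left) and Hes1 (right) in CPM in each library of the 4 groups, on linear axes that start at 0. Circles are replicate 1, triangles replicate 2 and lines the group mean; the 4 knockout libraries lie between 21.4 and 38.9 CPM of Rbpj, below the 4 wild-type libraries.

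In wild-type BMMs, genes of osteoclasts, of the NF-kB response and of inflammation were higher after 2 days with TNF than at day 0. Camera at its preset correlation called markers of resident macrophages and neutrophils lower as lists, with 1 of 24 and 1 of 14 members down. With an estimated correlation no list passed (adjusted p = 0.376 for resident macrophage and 0.720 for neutrophil markers). Mmp9, a matrix metalloproteinase made by osteoclasts, rose from 12.5 ± 0.936 to 3747 ± 1373 CPM (mean ± SD, n = 2), a log2 change of 8.12 ± 0.33 (limma adjusted p = 0.00128). Acp5, the tartrate-resistant acid phosphatase of osteoclasts (GRCm38 chromosome 9, 22126727 to 22135711), rose from 15.6 ± 6.25 to 805 ± 237 CPM. Mrc1, the mannose receptor, fell from 1297 ± 226 to 96.5 ± 13.2 CPM, by a log2 change of -3.74 ± 0.28 (limma adjusted p = 0.010).

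The largest increases among the genes named by rule were those of Saa3, an acute-phase protein (8.75 on the log2 scale), Ptges, which makes prostaglandin E2 (8.14), Mmp9 (8.12), Irg1, the itaconate-producing enzyme also called Acod1 (8.10), and the cystine transporter Slc7a11 (7.17). Next came the neutrophil-attracting chemokine Cxcl3 (6.87), the C-type lectin Clec4e (6.61), haptoglobin (Hp, 6.38), Slc6a12 (6.35) and complement C3 (6.04). The largest decreases were those of Slco2b1 (-6.88), the Fc receptor-like Fcrls (-6.52), Cbr2 (-5.07), Ctnnd2 (-4.53), and the chemokine receptor Ccr2 (-4.32). Next came Id1 and Id3, inhibitors of basic helix-loop-helix factors (-4.32 and -4.20), the ectonucleotidase Entpd1 (-4.11), the nuclear receptor Pparg (-3.98) and Mrc1 (-3.74). Each of these passed in limma, with adjusted p from 0.00128 (Mmp9) to 0.0484 (Saa3).

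Of the osteoclast list, 7 of 24 members rose (13 when adjusted over the list alone, and 13 with the block). The list median was 1.79 log2 (camera adjusted p = 9.23e-15, and adjusted p = 0.250 with an estimated correlation). Members that rose included Src, a kinase of the osteoclast sealing zone (5.37), and the fusion receptor Dcstamp (4.62). Ctsk, the collagen-degrading cathepsin, went from 17.8 ± 17.4 to 622 ± 460.2 CPM (adjusted p = 0.0961, and 0.00235 with the block), and Nfatc1, the master regulator of osteoclasts, from 75.3 ± 11.4 to 211 ± 95.8 CPM (adjusted p = 0.170, and 0.0517 with the block). Of the NF-kB and TNF response list, 9 of 33 members rose (16 rose and 2 fell when adjusted over the list alone, and 18 and 2 with the block). The list median was 1.89 (camera adjusted p = 2.35e-17, and adjusted p = 0.0708 with an estimated correlation). Examples were Cxcl2 (4.47), the signalling adaptor Traf1 (4.25), superoxide dismutase Sod2 (3.90) and the NF-kB inhibitors Nfkbie (3.82) and Nfkbia (2.66). The list of inflammatory cytokines and enzymes had 3 of 20 members up and a median of 1.63 (camera adjusted p = 2.63e-08, and adjusted p = 0.284 with an estimated correlation). The hypoxia and oxidative stress list had 1 of 21 up and a median of 0.95 (camera adjusted p = 8.20e-07, and adjusted p = 0.0708 with an estimated correlation).

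Markers of resident macrophages had 1 of 24 members down, Maf (-2.11), and a median of -1.06 (camera adjusted p = 0.00468, and adjusted p = 0.376 with an estimated correlation). Neutrophil markers moved with TNF as well. Elane, neutrophil elastase, fell by 3.31 on the log2 scale (adjusted p = 0.0443), the list median was -2.28 over 14 genes (camera adjusted p = 5.35e-05, and adjusted p = 0.720 with an estimated correlation), and 8 members were lower with the block. All 40 cell cycle genes had a negative log2 change (median -1.29; camera adjusted p = 2.22e-06, and adjusted p = 0.725 with an estimated correlation), with 0 called without and 4 called with the block. Nuclear genes of oxidative phosphorylation had a median of 0.38 and 0 members called (camera adjusted p = 6.97e-06, and adjusted p = 0.720 with an estimated correlation). Camera also called MHC class I presentation (median 0.55; camera adjusted p = 0.00201, and adjusted p = 0.720 with an estimated correlation), interferon-gamma and GBP genes (median 0.51; camera adjusted p = 0.0169, and adjusted p = 0.732 with an estimated correlation) and cholesterol synthesis (median -0.78; camera adjusted p = 0.00101, and adjusted p = 0.725 with an estimated correlation). With the block it called glycolysis (adjusted p = 0.00236) and stromal markers (0.0148) too, and neither passed with an estimated correlation (adjusted p = 0.637 for each). After median-ratio and quantile scaling the interferon-gamma and GBP (0.0626 and 0.0527) list lost its call (camera adjusted p in that order). Without wild-type day 0 replicate 1, the interferon-gamma and GBP (0.301) and cholesterol synthesis (0.479) lists lost their calls (camera adjusted p in parentheses). The interferon-gamma and GBP (0.572), MHC class I presentation (0.426) and cholesterol synthesis (0.316) lists lost their calls without wild-type TNF replicate 2. Of genes fixed by name, Tnf had 23.4 ± 7.05 and 65.6 ± 38.8 CPM at day 0 and with TNF, and Irf8 166 ± 73.0 and 131 ± 41.0. At the same times Myc had 49.9 ± 11.6 and 46.6 ± 46.0, Cxcl10 12.2 ± 14.3 and 14.7 ± 9.30, and Arg1 13.5 ± 7.47 and 32.7 ± 45.9. None of these 5 passed limma without the block. Nos2 had 2 reads over both day 0 libraries and 426 with TNF, a ratio of 196 (95% counting interval 53.8 to 1620.3; limma adjusted p = 0.219, and 0.0439 with the block). Il6 and Ifnb1 did not pass the expression filter.

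In total, TNF raised 99 and lowered 45 of 12194 genes in wild type (limma, Benjamini-Hochberg adjusted p under 0.05), and with the replicate block it raised 676 and lowered 574. Leaving out any 1 library lowered the count, to between 0, without wild-type day 0 replicate 2, and 84. It was 1 without wild-type day 0 replicate 1, 28 and 2 without wild-type TNF replicates 1 and 2, 84 without either knockout day 0 library and 67 without either knockout TNF library. With the block the count was 246 without wild-type day 0 replicate 2, 251 and 724 without wild-type TNF replicates 2 and 1. Of the 34 genes called without the block and named here, between 5 and 34 lost that call when 1 library was left out. The count was 28 within the 4 libraries of the contrast, 60 by edgeR and 874 by DESeq2 on the recovered reads.

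In Rbpj-knockout BMMs, osteoclast, nuclear oxidative phosphorylation and NF-kB response genes were higher after 2 days with TNF than at day 0. Markers of resident macrophages and neutrophils were lower, with 7 of 24 and 5 of 14 called. The calls of these 5 lists by camera were lost with an estimated correlation (adjusted p = 0.214 for osteoclast genes to 0.505 for neutrophil markers). Ctsk (GRCm38 chromosome 3, 95499256 to 95509362) rose from 6.09 ± 1.94 to 8915 ± 9278 CPM (mean ± SD, n = 2), a log2 change of 9.87 ± 1.12 (limma adjusted p = 0.00898). Acp5 rose from 41.4 ± 32.1 to 7586 ± 3696 CPM, Nfatc1 (GRCm38 chromosome 18, 80606205 to 80713071) from 83.3 ± 7.78 to 1099 ± 306 CPM, and Mmp9 from 14.4 ± 0.145 to 10424 ± 2927 CPM. Fcrls fell from 347 ± 117 to 0.361 ± 0.0632 CPM, a log2 change of -8.62 ± 0.32 (limma adjusted p = 3.22e-04).

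The other genes with the largest increases were Mt3, a metallothionein (8.09 on the log2 scale), Kbtbd11 (7.69), the sodium-proton exchanger Slc9b2 (7.65), the fusion proteins Dcstamp (7.53) and Ocstamp (7.30), the sphingosine-1-phosphate transporter Spns2 (7.15) and Rufy4. Rufy4 had 3 reads over both day 0 libraries and 4921 after TNF, a ratio of 2874 (95% counting interval 983 to 13941). Decreases included Rnase4 (-6.08), the chemokine receptor Ccr2 (-4.86), the high-affinity IgG receptor Fcgr1 (-5.49), the neutrophil granule genes Ltf (-5.55), Ngp (-5.34) and Mpo (-5.31), and Id1 (-5.29) and Id3 (-3.16). Slco2b1 had 4277 reads at day 0 and 2 after TNF, a ratio of 8.19e-04 (interval 9.92e-05 to 0.00296). Adjusted p in limma ran from 3.22e-04 (Fcrls) to 0.0341 (Ngp) over these genes.

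Of the osteoclast list, 14 of 24 members rose (21 when adjusted over the list alone, and 20 with the block), each of the 24 had a positive log2 change, and the median was 4.12 (camera adjusted p = 5.12e-23, and adjusted p = 0.214 with an estimated correlation). Of the 36 nuclear genes of oxidative phosphorylation measured, 12 rose (28 when adjusted over the list alone, and 35 with the block), with a median of 1.24 (camera adjusted p = 3.46e-19, and adjusted p = 0.277 with an estimated correlation). Without knockout day 0 replicate 2, 17 of them were called with the block. Members that rose included Uqcrfs1 (1.94) and Uqcrc2 (1.90) of complex III, Ndufs1 of complex I (1.62) and cytochrome c, Cycs (1.62). Of the NF-kB and TNF response list, 10 of 33 rose (13 rose and 2 fell when adjusted over the list alone, and 15 and 3 with the block), with a median of 0.61 (camera adjusted p = 1.10e-05, and adjusted p = 0.214 with an estimated correlation). Examples were Cxcl2 (3.57), Traf1 (3.58), Sod2 (2.88), Nfkbia (2.64) and the ubiquitin-editing Tnfaip3 (2.21). The inflammatory list had 3 of 20 members up, Irg1 (5.88), Ptges (5.57) and the cytokine Lif (5.48), and a median of 0.71 (camera adjusted p = 0.0218, and adjusted p = 0.592 with an estimated correlation).

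Resident macrophage markers had 7 of 24 members down (9 when adjusted over the list alone, and 14 with the block), with a median of -2.10 (camera adjusted p = 6.21e-06, and adjusted p = 0.214 with an estimated correlation). Among them were the Fc receptor Fcgr1 (-5.49), Apoe (-3.86), complement C1qc (-3.46) and Folr2 (-3.36). Outside this list, Mrc1 fell too (-3.60). Neutrophil markers had 5 of 14 down and a median of -2.37 (camera adjusted p = 1.03e-06, and adjusted p = 0.505 with an estimated correlation). Elane had 728 reads at day 0 and 3 after TNF, a ratio of 0.00722 (95% counting interval 0.00149 to 0.0212). Of 40 type I interferon-stimulated genes measured, 0 were called without the block and 15 were lower with it, and the median was -1.32 (camera adjusted p = 0.0334, and adjusted p = 0.929 with an estimated correlation). Examples were Oas3, from 51.7 and 691 CPM to 22.1 and 98.2 CPM in replicates 1 and 2, and Slfn8, from 24.3 and 254 to 11.1 and 47.6 CPM. The transcription factor Irf8 (-2.04), which restrains osteoclast formation, passed with the block (limma adjusted p = 8.75e-04) and not without it (0.0574). Cell cycle genes had a median of -1.14 (camera adjusted p = 2.18e-04, and adjusted p = 0.812 with an estimated correlation; 13 of 40 lower with the block), and B-lymphoid markers, over 5 genes, -1.55 (camera adjusted p = 0.0118, and adjusted p = 0.579 with an estimated correlation). With the block, camera called erythroid and megakaryocyte markers too (adjusted p = 0.0290, and adjusted p = 0.625 with an estimated correlation). Without knockout day 0 replicate 1, the inflammatory cytokines and enzymes (0.134) and cell cycle (0.164) lists lost their calls (camera adjusted p in parentheses). The type I interferon-stimulated (0.537) list lost its call without knockout day 0 replicate 2. Without knockout TNF replicate 1, the type I interferon-stimulated (0.931) and B lymphoid (0.10) lists lost their calls. The cell cycle (0.311) list lost its call without knockout TNF replicate 2. Tpsab1, a mast cell tryptase, had 2 reads at day 0 and 70 after TNF, a ratio of 61.3 (interval 16.4 to 516).

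In total, TNF raised 377 and lowered 245 of 12194 genes in the knockout (limma, adjusted p under 0.05), and with the block it raised 1486 and lowered 1676. The majority direction of the blocked calls turned with the scaling, at 1688 higher and 1508 lower after median-ratio rescaling, and with the tool, at 1601 and 1473 by edgeR. Leaving out any 1 library gave counts from 43, without knockout day 0 replicate 2, to 513. It was 50 and 202 without knockout TNF replicates 2 and 1, 135 without knockout day 0 replicate 1, and 285 and 282 without wild-type day 0 replicates 1 and 2. With the block the count was 898 and 1452 without knockout day 0 replicates 2 and 1, and 1240 without knockout TNF replicate 2. Of 50 named calls without the block, between 5 and 35 were lost when 1 library was left out. The count was 71 within the 4 libraries of the contrast and 1701 by DESeq2. Of the genes raised in wild type, 66 of 99 were also raised in the knockout, against 3.06 for independent lists, and of the 45 lowered, 42 were also lowered, against 0.904. The 2 genotypes share no libraries, but they share the replicate experiments and 1 estimate of the spread of each gene. The values for independent lists leave this out, so the excess over them is not a measure of a shared response.

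**Figure D2:**
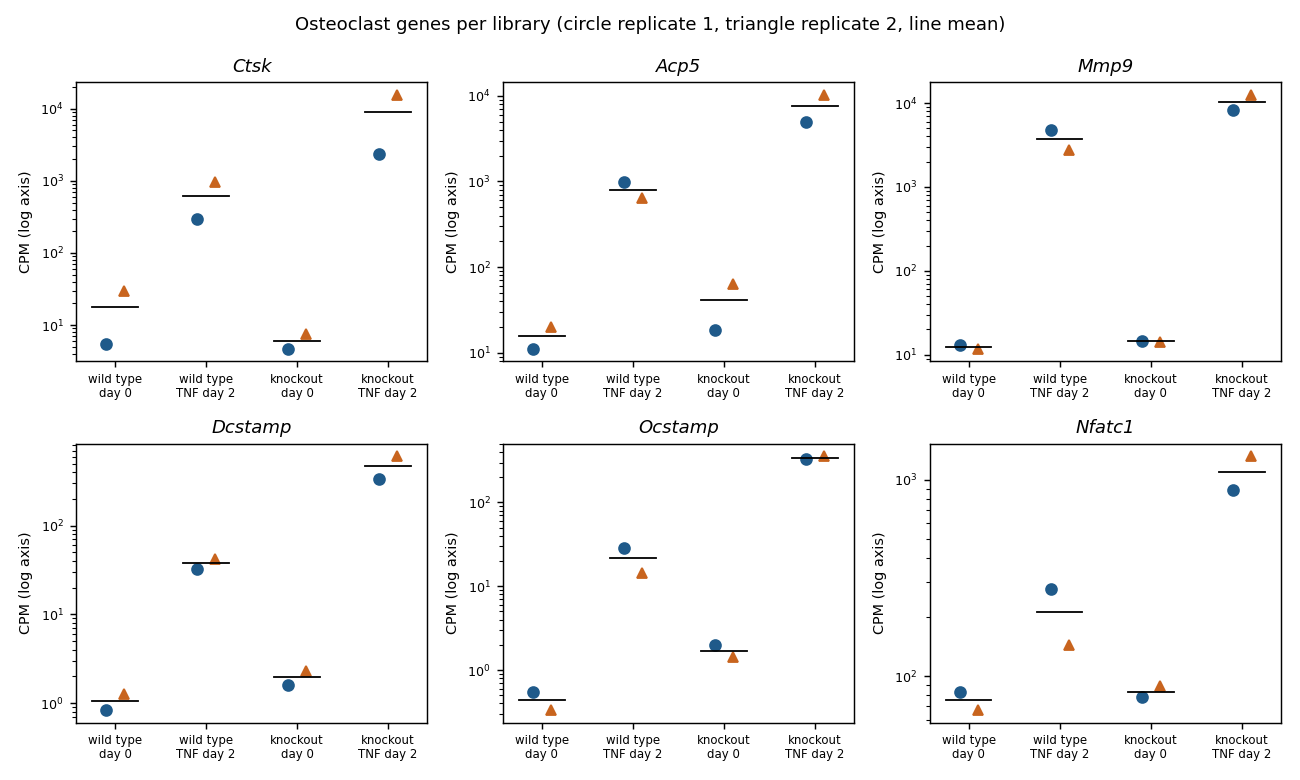
Osteoclast genes Ctsk, Acp5, Mmp9, Dcstamp, Ocstamp and Nfatc1 in CPM in each library, on log axes. Circles are replicate 1, triangles replicate 2 and lines the mean of the 2 libraries; in each panel both knockout libraries with TNF lie above both wild-type libraries with TNF.

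At day 0, before TNF, genes of MHC class II presentation and interferon-gamma response were called higher in the knockout, as lists, by camera at its preset correlation, and cell cycle genes lower. These calls were lost with an estimated correlation (adjusted p = 0.369, 0.482 and 0.715), and the median of the cell cycle genes was -0.017 in replicate 1 and -1.35 in replicate 2. Rbpj was the only gene to pass limma with the replicate block, and 0 of 12194 passed without it, while DESeq2 with the block called 188. H2-Ab1, an MHC class II chain, had 8.47 ± 2.08 CPM in wild type and 27.6 ± 18.5 CPM in the knockout (mean ± SD, n = 2), and H2-Eb1 had 18.1 ± 0.0700 and 61.1 ± 39.8 CPM. Mki67, a proliferation marker, had 767 ± 4.04 and 457 ± 349 CPM.

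The median log2 difference, knockout minus wild type, was 1.01 over 14 MHC class II genes (camera adjusted p = 1.40e-10, and adjusted p = 0.369 with an estimated correlation) and 1.06 over 24 interferon-gamma and GBP genes, all of which were positive (camera adjusted p = 1.15e-08, and adjusted p = 0.482 with an estimated correlation). MHC class I genes had a median of 0.46 (camera adjusted p = 1.95e-06, and adjusted p = 0.482 with an estimated correlation), and type I interferon-stimulated genes, each of 40 positive, 0.61 (camera adjusted p = 0.00522, and adjusted p = 0.801 with an estimated correlation). Dendritic cell markers moved with these lists, with a median of 0.72 over 13 genes (camera adjusted p = 5.30e-05, and adjusted p = 0.482 with an estimated correlation); Siglech, a plasmacytoid dendritic cell lectin, stood at 1.06 and 1.19 CPM in wild type and 2.47 and 10.8 CPM in the knockout. Monocyte genes had a median of 0.60 (camera adjusted p = 7.10e-05, and adjusted p = 0.369 with an estimated correlation) and included Treml4, at 9.50 ± 2.35 and 49.0 ± 31.5 CPM. The cell cycle list had a median of -0.71, with all 40 members negative (camera adjusted p = 2.36e-07, and adjusted p = 0.715 with an estimated correlation). Further lists called by camera were the NF-kB and TNF response (median 0.35; camera adjusted p = 2.58e-04, and adjusted p = 0.369 with an estimated correlation), inflammatory cytokines and enzymes (0.50; camera adjusted p = 0.00140, and adjusted p = 0.482 with an estimated correlation), interferon genes and induction machinery (0.21; camera adjusted p = 0.00592, and adjusted p = 0.482 with an estimated correlation) and the Notch pathway and RBP-J targets (0.44; camera adjusted p = 0.00592, and adjusted p = 0.482 with an estimated correlation). The last included the Deltex ligase Dtx4, at 125 ± 22.3 and 227 ± 77.9 CPM. Cholesterol synthesis (-0.35; camera adjusted p = 0.00180, and adjusted p = 0.715 with an estimated correlation), neutrophil markers (0.37; camera adjusted p = 0.0117, and adjusted p = 0.715 with an estimated correlation) and ribosomal protein genes (0.16; camera adjusted p = 0.00592, and adjusted p = 0.799 with an estimated correlation) were called too. With the block, camera also called glycolysis (adjusted p = 0.00882), apoptosis and survival (0.0478) and endothelial markers (0.0295). None of the 3 passed with an estimated correlation (adjusted p = 0.514, 0.576 and 0.460). Leaving out 1 library gave from 6 lists past the threshold, without knockout day 0 replicate 2, to 17, against 14. Without wild-type day 0 replicate 2, the Notch pathway and RBP-J targets (0.247) and ribosomal protein (0.184) lists lost their calls (camera adjusted p in parentheses). The Notch pathway and RBP-J targets (0.626) and ribosomal protein (0.438) lists lost their calls without knockout day 0 replicate 1. Without knockout day 0 replicate 2, calls were lost by the NF-kB and TNF response, inflammatory cytokines and enzymes, and interferon-gamma and GBP lists. So were those of the interferon and induction machinery, MHC class I presentation, monocyte, cholesterol synthesis, cell cycle, neutrophil and dendritic lists. The type I interferon-stimulated list turned direction. That fit, without the block, set knockout replicate 1 alone against both wild-type replicates. In wild type at day 0 the type I list stood 2.48 log2 higher in replicate 2 than in replicate 1. Its difference between genotypes within replicate 1 was 0.29. The inflammatory cytokines and enzymes (0.253), type I interferon-stimulated (0.0511), interferon and induction machinery (0.176), cholesterol synthesis (0.192) and neutrophil (0.415) lists lost their calls without wild-type day 0 replicate 1. The MHC class II list was called whichever library was left out.

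Osteoclast genes had, at day 0, a median difference between genotypes of 0.097 and 0 members called (camera adjusted p = 0.0647). Nfatc1 differed by 0.15 ± 0.38, Acp5 by 1.18 ± 0.66 and Ctsk by -1.07 ± 1.12 on the log2 scale (± standard error). None of the 3 passed limma with or without the block. The chemokine Ccl2 stood at 348 and 478 CPM in wild type and 193 and 28.1 CPM in the knockout, and Id3 at 32.2 ± 9.32 and 85.1 ± 20.9 CPM (mean ± SD). At an unadjusted p under 0.05, limma gave 164 of 12194 genes at day 0. This is a smaller share than the 0.05 that falls under this cut when no gene differs. Adjusted calls numbered 0 by edgeR and 24 by DESeq2. With the block the count was 1 by limma, 1 by edgeR and 188 by DESeq2, and Rbpj lost its blocked call when any of 6 libraries was left out, among them wild-type day 0 replicate 2 (adjusted p = 0.314) and knockout day 0 replicate 2 (0.729).

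After TNF, 16 of 24 osteoclast genes and 26 of 36 oxidative phosphorylation genes were higher in knockout than in wild-type BMMs in the fit with the block, and none of them without it. These numbers fell to 0 and 0 without wild-type TNF replicate 2, and to 3 and 0 without knockout TNF replicate 2, where the median difference of the osteoclast genes was 1.85 and 2.00 log2, against 2.20. Camera at its preset correlation called hypoxia, MHC class I and resident macrophage genes lower as lists, with 0 members called without the block. With an estimated correlation no list passed (adjusted p = 0.268, 0.435 and 0.309 for these 3). Ctsk stood at 622 ± 460.2 CPM in wild type and 8915 ± 9278 CPM in the knockout (mean ± SD, n = 2), Acp5 at 805 ± 237 and 7586 ± 3696 CPM, Dcstamp (GRCm38 chromosome 15, 39745930 to 39760938) at 37.5 ± 6.79 and 469.9 ± 187 CPM, and Nfatc1 at 211 ± 95.8 and 1099 ± 306 CPM. Without the block only Mst1r, a receptor tyrosine kinase (GRCm38 chromosome 9, 107906873 to 107920383), passed among all genes, at 1.01 ± 0.114 and 49.2 ± 7.75 CPM (log2 difference 5.03 ± 0.36, limma adjusted p = 0.0442). This split of 1 higher and 0 lower was 1 and 1 after median-ratio rescaling, and 3 and 1 after quantile normalization. With the block 674 genes were higher and 457 lower in the knockout.

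Of the osteoclast list, 0 of 24 members passed over all genes without the block, 18 when adjusted over the list alone and 16 with the block, all higher in the knockout. The list median was 2.20 (camera adjusted p = 9.14e-18, and adjusted p = 0.268 with an estimated correlation). With the block, the log2 difference was 3.58 ± 0.20 for Dcstamp (limma adjusted p = 0.00339), 4.04 ± 0.28 for Ocstamp (adjusted p = 0.00669), and 4.35 ± 0.27 for the integrin chain Itgb3 (adjusted p = 0.00417). It was 3.18 ± 0.49 for Acp5 (adjusted p = 0.0228), 3.51 ± 0.46 for Ctsk (adjusted p = 0.0194) and 2.42 ± 0.35 for Nfatc1 (adjusted p = 0.0203). Without the block their adjusted p lay between 0.0735 (Ocstamp) and 0.295 (Ctsk). Further genes higher with the block were Mt3 (4.36), Trim54 (4.55), the thrombin receptor F2r (4.35), the calcitonin receptor Calcr (4.27), Nyap2 (4.27), Sorbs2 (4.11), Dgki (3.94) and the osteoclast receptor Oscar (3.77). Of 36 nuclear oxidative phosphorylation genes, each had a positive difference, with a median of 0.90 (camera adjusted p = 1.66e-17, and adjusted p = 0.309 with an estimated correlation), 0 called without the block, 17 when adjusted over the list alone and 26 with the block. The last number was 14 and 15 without wild-type day 0 replicates 1 and 2, 9 without wild-type TNF replicate 1, 8 without either knockout day 0 library, and 0 without replicate 2 of either TNF group. Without wild-type TNF replicate 2 no gene of any list passed with the block. Uqcrc2 was higher by 1.54 and, on the lysosome list, the vacuolar proton pump subunit Atp6v1b2 by 2.03 (blocked adjusted p = 0.0180 and 0.0166, and 0.201 and 0.161 without the block).

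Lower with the block in the knockout were Iqgap2 (-3.81), Uchl1 (-3.71), the sialic acid receptor Siglec1 (-3.27), podoplanin (Pdpn, -3.24), the desaturase Scd1 (-3.22), Saa3 (-3.19), Hp (-3.14) and complement C1s1 (-2.96). None of these passed without the block (adjusted p from 0.135 to 0.596). Lyz1 (-3.23) and Lyz2 (-1.45) are near-identical paralogs that can lose or swap reads, so their values are uncertain. Lyz2 is also the locus that holds Cre, so its lower level in the knockout cannot be ascribed to Rbpj loss. Hypoxia and oxidative stress genes had a median of -0.85 (camera adjusted p = 1.31e-04, and adjusted p = 0.268 with an estimated correlation), with 4 of 21 lower with the block, among them Hif1a (-1.49) and heme oxygenase Hmox1 (-1.64). Resident macrophage markers had a median of -0.86 (camera adjusted p = 4.68e-04, and adjusted p = 0.309 with an estimated correlation), MHC class I genes -0.60 (camera adjusted p = 5.87e-04, and adjusted p = 0.435 with an estimated correlation), and type I interferon-stimulated genes -0.74 (camera adjusted p = 0.0440, and adjusted p = 0.821 with an estimated correlation), the last with 0.066 in replicate 1 and -1.50 in replicate 2. The NF-kB list had a median of -0.36 (camera adjusted p = 0.0104, and adjusted p = 0.373 with an estimated correlation). Ikbke, a kinase on the list of interferon induction machinery, stood at 323 ± 9.08 and 124 ± 3.85 CPM. The transcription factor Irf8 stood at 131 ± 41.0 and 46.0 ± 17.9 CPM (blocked adjusted p = 0.0165, and 0.272 without the block), while Id3, at 1.28 ± 0.491 and 9.28 ± 3.51 CPM, was higher with the block. Mast cell marker Tpsab1 stood at 0.140 and 0 CPM in wild type and 2.33 and 2.48 CPM in the knockout. Without wild-type TNF replicate 2, the NF-kB and TNF response and MHC class I presentation lists lost their calls. The type I interferon-stimulated list turned direction. That fit, without the block, set wild-type replicate 1 alone against both knockout replicates. In the knockout with TNF the type I list stood 1.96 log2 higher in replicate 2 than in replicate 1. The NF-kB and TNF response and type I interferon-stimulated lists lost their calls without knockout TNF replicate 1.

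Camera further called chemokines (median -0.71; camera adjusted p = 0.0174, and adjusted p = 0.435 with an estimated correlation) and interferon induction machinery (median -0.58; camera adjusted p = 0.00107, and adjusted p = 0.309 with an estimated correlation). It called cholesterol efflux genes (median -0.65; camera adjusted p = 0.0306, and adjusted p = 0.373 with an estimated correlation) and monocyte genes (median -0.39; camera adjusted p = 0.0460, and adjusted p = 0.373 with an estimated correlation). Further calls were osteoclast repressors (median -0.30, camera adjusted p = 0.0460, and adjusted p = 0.373 with an estimated correlation) and cell cycle genes (median -0.54, camera adjusted p = 0.0104, and adjusted p = 0.821 with an estimated correlation). The osteoclast repressor list holds Rbpj, the deleted gene, at -2.96, so part of its call was set by the genotype. The list was not tested without Rbpj. It also called B-lymphoid markers (median -0.68; camera adjusted p = 0.0460, and adjusted p = 0.583 with an estimated correlation) and mast cell and basophil markers (median 1.05; camera adjusted p = 0.0460, and adjusted p = 0.435 with an estimated correlation), and immediate early and heat shock genes (median -0.48; camera adjusted p = 0.0460, and adjusted p = 0.583 with an estimated correlation). With the block the B-lymphoid and mast cell lists no longer passed (camera adjusted p = 0.0815 and 0.0940), and ribosomal protein genes did (0.0158, and adjusted p = 0.767 with an estimated correlation). Leaving out 1 library gave from 7 lists past the threshold, without wild-type TNF replicate 2, to 19, against 16. After median-ratio and quantile scaling 10 lists passed, and the osteoclast repressors (0.0544 and 0.0508), type I interferon-stimulated (0.0754 and 0.0957), monocyte (0.0714 and 0.0855), B lymphoid (0.0714 and 0.0855), mast and basophil (0.0504 and 0.0529) and immediate early and heat shock (0.0714 and 0.0651) lists lost their calls in both (camera adjusted p in that order). Without wild-type TNF replicate 1, the osteoclast repressors (0.0721), cell cycle (0.834) and mast and basophil (0.325) lists lost their calls (camera adjusted p in parentheses). The osteoclast repressors (0.0756), chemokines (0.657), interferon and induction machinery (0.199), monocyte (0.514), cholesterol efflux and LXR (0.0631), B lymphoid (0.957) and immediate early and heat shock (0.284) lists lost their calls without wild-type TNF replicate 2. Without knockout TNF replicate 1, the osteoclast repressors (0.114), chemokines (0.229), interferon and induction machinery (0.113), monocyte (0.310) and B lymphoid (0.282) lists lost their calls. The cholesterol efflux and LXR (0.0533), cell cycle (0.110) and immediate early and heat shock (0.130) lists lost their calls without knockout TNF replicate 2. Without knockout day 0 replicate 1, the B lymphoid (0.0559) and mast and basophil (0.0537) lists lost their calls. The B lymphoid (0.0551) list lost its call without knockout day 0 replicate 2.

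At an unadjusted p under 0.05, limma gave 1372 genes without the block. The adjusted count of 1 was 0 by edgeR and 593 by DESeq2. The blocked count of 1131 was 811 by edgeR and 2318 by DESeq2, fell to 0 without wild-type TNF replicate 2 and to 8 without knockout TNF replicate 2, and the osteoclast genes called with the block then numbered 0 and 3. Without the other libraries it was 672 (wild-type day 0 replicate 1), 675 (wild-type day 0 replicate 2), 527 (wild-type TNF replicate 1), 403 (knockout day 0 replicate 1), 414 (knockout day 0 replicate 2) and 1107 (knockout TNF replicate 1). The call of Mst1r without the block was lost when any 1 library was left out (limma adjusted p 0.0962 to 0.708).

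The last comparison asked whether the TNF response itself differed with Rbpj loss. The osteoclast list rose more in the knockout and interferon-related lists had a more negative response by camera at its preset correlation, while no single gene passed. With an estimated correlation no list passed (adjusted p = 0.143 for osteoclast and 0.634 for type I interferon-stimulated genes). Dcstamp rose by 4.62 on the log2 scale in wild type and 7.53 in the knockout, a difference of 2.92 ± 0.56 (limma adjusted p = 0.641, and 0.0593 with the block). Nfatc1 differed by 2.27 ± 0.53 (adjusted p = 0.771, and 0.120 with the block), and Ctsk by 4.58 ± 1.59 (adjusted p = 0.829, and 0.104 with the block). Irf8 went the other way, by -1.74 ± 0.64 (adjusted p = 0.838, and 0.103 with the block). Mst1r (5.12) and Itgb3 (4.44) had limma adjusted p = 0.0537 with the block, the lowest value any gene reached.

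All 24 osteoclast genes had a more positive response in the knockout, with a median difference of 1.85 (camera adjusted p = 1.80e-16, and adjusted p = 0.143 with an estimated correlation), and 6 passed when adjusted over the list alone. Nuclear oxidative phosphorylation genes, all 36 positive, had 0.86 (camera adjusted p = 2.01e-16, and adjusted p = 0.189 with an estimated correlation). Type I interferon-stimulated genes, all 40 negative, had -1.38 (camera adjusted p = 6.13e-04, and adjusted p = 0.634 with an estimated correlation), but the median was -0.28 in replicate 1 and -2.47 in replicate 2. Interferon-gamma and GBP genes had -1.23 (camera adjusted p = 8.26e-05, and adjusted p = 0.456 with an estimated correlation), with -0.31 in replicate 1 and -2.19 in replicate 2, and NF-kB and TNF response genes -0.67 (camera adjusted p = 2.37e-05, and adjusted p = 0.143 with an estimated correlation), with -0.30 in replicate 1 and -1.11 in replicate 2. The number of genes at an unadjusted p under 0.05 was 689 without and 2192 with the block, of 12194. The first is close to the share of 0.05 that falls under this cut when no gene differs. edgeR gave 0 adjusted calls with and without the block, and DESeq2 gave 78 and, with the block, 997. Without knockout TNF replicate 1 the blocked limma count was 322, and it was 0 without any other library. With the block, camera also called dendritic markers (adjusted p = 0.0411) and immediate early and heat shock genes (0.0228), and neither passed with an estimated correlation (adjusted p = 0.441 and 0.387). Without wild-type TNF replicate 2, 12 lists passed, against 19. Without wild-type day 0 replicate 1, the type I interferon-stimulated (0.672) list lost its call (camera adjusted p in parentheses). The type I interferon-stimulated (0.352) and interferon-gamma and GBP (0.312) lists lost their calls without wild-type TNF replicate 2. Without knockout day 0 replicate 2, the type I interferon-stimulated (0.768) and interferon-gamma and GBP (0.137) lists lost their calls. The type I interferon-stimulated (0.547) and interferon-gamma and GBP (0.0990) lists lost their calls without knockout TNF replicate 1. The osteoclast and oxidative phosphorylation lists passed whichever library was left out.

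**Figure D3:**
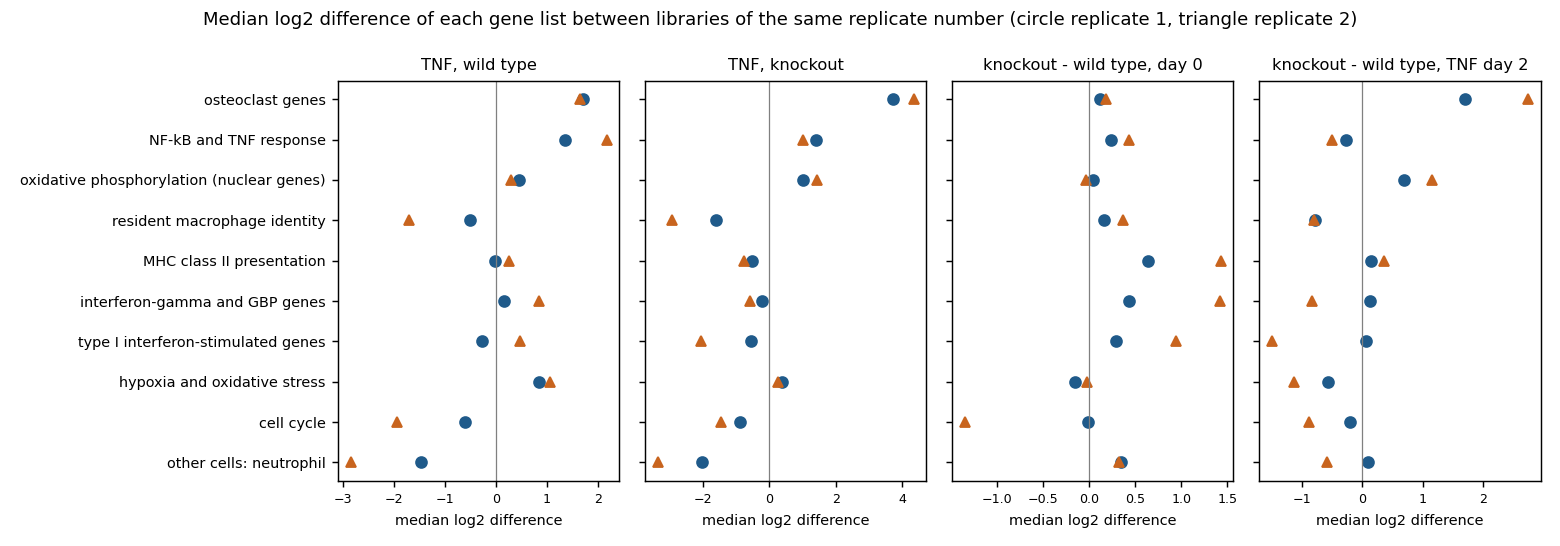
Median log2 difference of 10 gene lists between libraries of the same replicate number, for TNF in wild type, TNF in the knockout, and knockout minus wild type at day 0 and after TNF. Circles are replicate 1 and triangles replicate 2; osteoclast genes lie to the right of 0 in both replicates for both TNF responses and for the knockout after TNF.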

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

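The 2 tests on thinned reads were fixed before their results were seen, and the other 5 tests of explanations were chosen after. Of 33 gene lists, 19 responded differently to TNF in the knockout and in wild type by camera's test of the difference of responses at its preset correlation, and none of the 19 passed with an estimated correlation (adjusted p 0.143 to 0.634). The 3 with a more positive response in the knockout were osteoclast genes (1.80e-16), oxidative phosphorylation (nuclear genes) (2.01e-16), cholesterol synthesis (0.00671), with the camera adjusted p of each in parentheses. The median TNF change of cholesterol synthesis genes was -0.78 in wild type and -0.19 in the knockout, and its call was lost without wild-type day 0 replicate 1 (0.871), without wild-type TNF replicate 2 (0.800), without knockout day 0 replicate 2 (0.164). The 16 with a less positive or more negative response were MHC class I presentation (8.47e-08), interferon genes and induction machinery (9.90e-06), NF-kB and TNF response (2.37e-05), monocyte genes (6.59e-05), interferon-gamma and GBP genes (8.26e-05), resident macrophage identity (2.13e-04), hypoxia and oxidative stress (3.19e-04), type I interferon-stimulated genes (6.13e-04), inflammatory cytokines and enzymes (0.00162), B lymphoid markers (0.00405), osteoclast repressors (0.00671), cholesterol efflux and LXR genes (0.0106), neutrophil markers (0.0215), MHC class II presentation (0.0244), matrix and tissue remodelling (0.0423), apoptosis and survival (0.0471). Leaving out 1 library ended 9 (wild-type TNF replicate 2), 7 (knockout day 0 replicate 2), 6 (wild-type day 0 replicate 1), 5 (knockout TNF replicate 1), 1 (knockout TNF replicate 2), 1 (knockout day 0 replicate 1), 1 (wild-type day 0 replicate 2) of these 19 calls at the preset correlation. Matrix and tissue remodelling lost its call without replicate 1 of either day 0 group or replicate 2 of either TNF group. MHC class II, apoptosis and neutrophil lists each lost theirs without wild-type day 0 replicate 1, wild-type TNF replicate 2 or knockout day 0 replicate 2. The first 2 of these also lost it without knockout TNF replicate 1. The median difference of responses was -0.31 in replicate 1 and -2.19 in replicate 2 for interferon-gamma and GBP genes. It was -0.47 in replicate 1 and -1.72 in replicate 2 for MHC class I genes, and -0.24 and -2.00 for inflammatory genes. For cholesterol synthesis it was 0.17 in replicate 1 and 1.14 in replicate 2, and the TNF change in the knockout was -0.42 in replicate 1 and 0.24 in replicate 2. After median-ratio rescaling the apoptosis and survival (0.0631) and matrix and tissue remodelling (0.0806) lists lost their calls, the first also after quantile normalization (0.0546).

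Of the 140 genes reported here, 10 had a higher level with TNF in both wild-type replicates and a lower level with TNF in both knockout replicates. Random signs alone give this pattern for some genes, and its share over all genes was not counted. The number 10 is therefore no measure of opposite responses. The difference of the log2 responses was -0.80 for Cd14, -1.49 for Ier3, -0.79 for Ifi35, -1.24 for Irf1, -1.95 for Lyz1, -2.34 for Nfkbiz, -1.80 for Pfkfb3, -1.15 for Psmb8, -1.40 for Psmb9, -2.96 for Siglec1. Some of the rises in wild type were small. They were 0.38 and 0.025 log2 in replicates 1 and 2 for Siglec1, and 0.065 and 0.14 for Ifi35. Opposite directions were not tested as such, and the limma test of the difference of responses passed for none of the 10 genes. Reads of Lyz1 can be shared with Lyz2, so its value is uncertain.

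Osteoclast genes stood higher in the knockout than in wild type after TNF, with 16 of 24 called in the fit with the block and none without it. With an estimated correlation camera called no list in this comparison (lowest adjusted p = 0.268). After all libraries were thinned to the shallowest, 16 genes were called, and 16 were called in both. Thinning leaves the expected CPM unchanged, so this argues only against uneven counting noise between libraries as the source of the calls. For abundant genes taking the reads, the median difference was 2.13 for members outside the 50 most abundant genes. Reads so taken would shift all other genes alike, and the median difference over all genes was only 0.015 as deposited. Leaving the 50 out could therefore hardly change the result. It is the small median over all genes that argues against this cause. A mislabelled library is argued against by Rbpj, whose highest knockout level was 21.9% of the lowest wild-type level. An effect of Rbpj loss on the osteoclast response to TNF remains a hypothesis, found and tested on these libraries, and only 0 and 3 members were called without wild-type and knockout TNF replicate 2, with median differences of 1.85 and 2.00 log2 against 2.20.

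Type I interferon-stimulated genes had, as a list, a more negative TNF response in the knockout than in wild type by camera at its preset correlation (adjusted p = 0.634 with an estimated correlation). For a difference in depth, the median difference of responses was -1.38 after thinning, as before it. Thinning leaves the expected CPM unchanged, so this median could hardly move, and the test cannot decide on depth. A difference between the 2 experiments is a candidate explanation, since the median was -0.28 in replicate 1 and -2.47 in replicate 2. The pattern may therefore rest on 1 experiment, and a biological effect that differs in size between experiments was not tested apart from it.

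MHC class II and interferon-gamma and GBP genes stood higher in the knockout at day 0 as lists by camera at its preset correlation (adjusted p = 0.369 and 0.482 with an estimated correlation). A difference between the 2 experiments as the whole cause was tested on both lists together. Their median was 0.55 in replicate 1 and 1.42 in replicate 2. Alone, MHC class II genes had 0.64 and 1.43, and interferon-gamma and GBP genes 0.43 and 1.42. The 0.43 lies under the cut of the test, which was set after the data were seen. This cause is thus argued against for MHC class II genes only, from 1 pair of libraries per replicate. The GBP list also lost its call without knockout day 0 replicate 2. There, without the block, knockout replicate 1 alone was set against both wild-type replicates. In wild type at day 0 the GBP list stood 1.16 log2 higher in replicate 2 than in replicate 1. The lost call can come from that and does not decide on the cause. More dendritic cells in the knockout cultures remain open, since dendritic markers outside these lists had medians of 0.47 and 1.31 in the 2 replicates. Each of the 12 markers had reads in wild type as well, and the most abundant, Itgax, stood at 9.04 and 17.1 CPM in wild type and 13.2 and 72.1 CPM in the knockout. With 2 libraries per group, more dendritic cells and a change within the macrophages cannot be told apart.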

How the results depend on the processing

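The fits with the replicate block under other tools, scalings, thinned reads or fewer libraries were chosen after the results were seen. So was the block with an estimated correlation, and the other alternatives were chosen before. For thinned reads, the bounds of the 2 tests of explanations were written before the results of those tests were seen. The causes of the changes were not tested. Counts of called genes changed by over 1.5 times under these settings. Without a filter the count was 78 for TNF in wild type, 13 for Rbpj loss after TNF. With the replicate block the count was 1250 for TNF in wild type, 3162 for TNF in the knockout, 1 for Rbpj loss at day 0, 1131 for Rbpj loss after TNF. With only the libraries of the contrast the count was 28 for TNF in wild type, 71 for TNF in the knockout, 0 for Rbpj loss after TNF. With edgeR on recovered reads the count was 60 for TNF in wild type, 0 for Rbpj loss after TNF. With DESeq2 on recovered reads the count was 874 for TNF in wild type, 1701 for TNF in the knockout, 24 for Rbpj loss at day 0, 593 for Rbpj loss after TNF, 78 for the difference of responses. With replicate block, DESeq2 on recovered reads the count was 2545 for TNF in wild type, 188 for Rbpj loss at day 0, 2318 for Rbpj loss after TNF, 997 for the difference of responses. With a pseudocount of 0.1 the count was 0 for Rbpj loss after TNF. With a pseudocount of 2 the count was 21 for Rbpj loss after TNF. With a filter at 5 CPM the count was 0 for Rbpj loss after TNF. With median-ratio rescaling the count was 2 for Rbpj loss after TNF. With quantile normalization the count was 4 for Rbpj loss after TNF. Without the trend the count was 13 for Rbpj loss after TNF. With replicate block, reads thinned to the shallowest library the count was 3 for the difference of responses. The block turned no call of a named gene off: 92 of 264 reported values gained a call and 172 were the same, and it changed 11 list calls. The median log2 difference over all genes for TNF in wild type was -0.117 as deposited and 6.21e-04 after median-ratio rescaling.

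Rbpj did not pass in the limma fit with group as the only term, but passed under some other settings. At day 0 its log2 difference was then -2.60 (replicate block) and -2.61 (DESeq2 on recovered reads). After TNF it was -2.89 (pseudocount 2), -2.96 (no filter), -3.00 (median-ratio rescaling), -2.98 (quantile normalization), -2.96 (replicate block), -2.96 (eBayes without trend) and -3.02 (DESeq2 on recovered reads). Only the setting named replicate block held the block. Values not called without the block changed sign: Rbpj for TNF in wild type was 0.018 (median-ratio rescaling) and 0.0083 (edgeR) and 0.018 (DESeq2), Hes1 for TNF in wild type was -0.086 (quantile normalization), Arg1 for TNF in wild type was 1.24 (edgeR) and 1.25 (DESeq2), Arg1 for TNF in knockout was 0.21 (edgeR) and 0.27 (DESeq2), Myc for knockout minus wild type, after TNF was -0.0017 (quantile normalization), Arg1 for difference of TNF responses was -1.03 (edgeR) and -0.98 (DESeq2). Every one of the 69 list calls was lost with an estimated correlation: 0 lists passed in each contrast, and 0 also with the block and an estimated correlation, against 11, 9, 14, 16 and 19. With 4 or 3 residual degrees of freedom behind the estimate, this alternative could hardly pass. These losses therefore do not decide which calls hold. After TNF, median-ratio and quantile scaling each gave 10 lists for knockout against wild type. Over settings other than leaving out a library, 2801 values of named genes kept their direction and side of the threshold, 130 lost and 183 gained a call. Among values with 1 library left out, 1722 kept both, 319 lost and 3 gained a call and 56 changed sign. In the shallowest library, knockout TNF replicate 1, 3 reads amount to 0.304 CPM, which limits what low genes show.

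Leaving out 1 library gave these ranges of called genes: 0 to 84 for TNF in wild type, 246 to 1404 for TNF in wild type with the block, 43 to 513 for TNF in the knockout, 898 to 3070 for TNF in the knockout with the block, 0 to 2 for Rbpj loss at day 0 with the block, 0 to 0 for Rbpj loss after TNF, 0 to 1107 for Rbpj loss after TNF with the block, 0 to 322 for the difference of responses with the block. Lists past the threshold ranged over 11 to 17 for TNF in wild type, 8 to 16 for TNF in knockout, 6 to 17 for knockout minus wild type, day 0, 7 to 19 for knockout minus wild type, after TNF, 12 to 26 for difference of TNF responses. A group left with 1 library is assumed to vary like the other groups. In the fits without the block such a group held 1 replicate number and the other groups both. Differences between the replicate numbers therefore entered its contrasts, and a change of sign or a lost call there can come from them. The list tests with 1 library left out were all run without the block. Log2 values that changed sign, none called without the block, ranged for TNF in wild type over -0.28 to 0.067 (Rbpj), -0.090 to 0.35 (Hes1), -0.76 to 0.16 (Irf8), -4.11 to 2.34 (Arg1), -1.77 to 0.68 (Myc), -0.73 to 2.39 (Cxcl10). The values ranged for TNF in knockout over -4.65 to 0.85 (Ifit2), -0.052 to 0.58 (Tnf), -2.01 to 0.66 (Myc), -0.63 to 1.79 (Cxcl10), -2.50 to 1.52 (Arg1). The values ranged for knockout minus wild type, day 0 over -0.0047 to 0.30 (Nfatc1), -2.24 to 0.10 (Ctsk), -0.25 to 0.67 (Irf8), -0.53 to 3.22 (Mx2), -3.25 to 0.69 (Lyz1), -0.14 to 0.48 (Tnf), -1.57 to 0.35 (Lyz2), -0.42 to 0.78 (Myc), -1.17 to 1.96 (Cxcl10), -0.10 to 0.14 (Nos2). The values ranged for knockout minus wild type, after TNF over -3.74 to 0.12 (Slc16a3), -2.09 to 0.087 (Pfkl), -2.41 to 0.15 (Stat2), -1.28 to 1.39 (Myc), -0.52 to 0.81 (Cxcl10), -4.75 to 1.69 (Arg1), -3.16 to 0.10 (Nos2). The values ranged for difference of TNF responses over -1.80 to 0.12 (Lyz2), -1.46 to 1.21 (Myc), -1.81 to 1.31 (Cxcl10), -2.83 to 3.62 (Arg1), -3.18 to 0.086 (Nos2). Lists whose direction turned had camera adjusted p for TNF in wild type of 6.36e-07 to 0.539 (type I interferon-stimulated genes), 4.65e-06 to 0.572 (interferon-gamma and GBP genes). These were for TNF in knockout of 4.74e-08 to 0.931 (type I interferon-stimulated genes), 0.0190 to 0.983 (ribosomal protein genes). These were for knockout minus wild type, day 0 of 1.06e-12 to 0.0511 (type I interferon-stimulated genes), 3.43e-04 to 0.997 (interferon genes and induction machinery), 8.17e-06 to 0.359 (glycolysis), 3.09e-11 to 0.837 (cholesterol synthesis), 1.40e-06 to 0.604 (neutrophil markers), 2.17e-06 to 0.926 (stromal and osteoblast markers). These were for knockout minus wild type, after TNF of 2.98e-10 to 0.560 (type I interferon-stimulated genes), 8.38e-11 to 0.834 (cell cycle), 2.08e-04 to 0.957 (B lymphoid markers). These were for difference of TNF responses of 2.85e-12 to 0.768 (type I interferon-stimulated genes), 8.55e-06 to 0.892 (cell cycle), 0.00222 to 0.885 (ribosomal protein genes).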

Other observations

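The comparisons of replicate numbers were chosen after the data were seen. Replicate 2 held more transcripts of interferon-stimulated genes than replicate 1 in each of the 4 groups, with list medians of 1.96 to 3.28 log2 over 40 genes, replicate 2 minus replicate 1. Interferon-gamma and GBP genes were higher in replicate 2 by medians of 1.16 to 2.70, and dendritic markers by 0.48 to 1.56. Stromal and osteoblast markers went the other way, by -3.39 to -1.11, as did glycolysis genes (-1.23 to -0.77), cell cycle genes (-2.15 to -0.22), cholesterol synthesis genes (-1.45 to -0.049) and ribosomal protein genes (-0.87 to -0.21). These differences between replicate numbers were not tested.

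Other lists had no camera call in any contrast without the block. Genes of IL-4 type macrophages had medians of -0.88 for TNF in wild type, -1.10 for TNF in the knockout, -0.062 for Rbpj loss at day 0 and -0.40 after TNF. Glycolysis genes had medians of 0.33 for TNF in wild type, 0.44 for TNF in the knockout, -0.25 for Rbpj loss at day 0 and -0.23 after TNF. Lysosome and phagocytosis genes had medians of -0.23 for TNF in wild type, 0.13 for TNF in the knockout, 0.057 for Rbpj loss at day 0 and 0.014 after TNF. Genes of the unfolded protein and amino acid response had medians of -0.15 for TNF in wild type, 0.042 for TNF in the knockout, 0.021 for Rbpj loss at day 0 and 0.17 after TNF. Erythroid and megakaryocyte markers had medians of -1.29 for TNF in wild type, -2.40 for TNF in the knockout, 0.30 for Rbpj loss at day 0 and -0.62 after TNF. Endothelial markers had medians of -1.06 for TNF in wild type, -1.52 for TNF in the knockout, 0.19 for Rbpj loss at day 0 and -0.028 after TNF. Stromal and osteoblast markers had medians of 0.85 for TNF in wild type, 0.22 for TNF in the knockout, 0.022 for Rbpj loss at day 0 and -0.63 after TNF. The median of the lysosome list changed sign with the scaling for Rbpj loss after TNF. T and NK cell markers, with 2 genes kept, had medians of 1.23 and 0.73 for TNF in wild type and the knockout, and the 1 histone gene kept had -0.59 and 1.69.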
